A study of Mus musculus with 54 samples.

How the data were processed

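Methylated DNA was captured with an antibody against 5-methylcytosine from intestinal tissue of mice aged 15 to 19 weeks and sequenced on an Illumina Genome Analyser IIx, per the labels. The strains were C57BL/6 (B6), PWD/Ph (PWD), their F1 cross (B6xPWD), and B6 mice carrying PWD chromosomes. C5 mice carry a PWD chromosome 5 on a B6 genome, per the series design text. The labels also name C5F1 and C1_5F1 groups, whose crosses they do not spell out. Tissues were adenomas and normal mucosa of mice with the Min allele of Apc, and mucosa of wild type mice.

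The deposited table holds counts in 10535096 windows of 250 bp, with 1 column per library, per the file headers. The reads were aligned with BWA to mm10, per the submitters' processing notes; the BWA version and settings, the read filters and the counting tool are not given in the sources used here. No window of any library exceeded 500 counts, which equals 1 read per position and strand of a window. The table also gives a deposited CpG density score for each window, whose scale is not given in the sources used here; 420407 windows had no score and held 28151 reads in all. A score of 10 or more is called CpG-dense below.

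The labels list 54 samples, of which 47 are MeDIP and 7 are input. The table has columns for 46 MeDIP libraries and 1 input library, which is the B6xPWD adenoma sample 11_5. For sample 11_6 of B6xPWD the labels conflict: the MeDIP library is named normal mucosa of Apc Min mice and the input library wild type. The name of the MeDIP library was followed. The MeDIP sample 12_10 of C5F1 wild type and the other 6 input samples were not used here. Total counts per MeDIP library ran from 8358806 to 27842607. The highest 1000 windows of a library held at most 0.655% of its counts.

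Windows were summed over gene ends with the positions of 20665 protein-coding autosomal genes in the GRCm38.p6 annotation, the same build as mm10. That annotation file gives no strand, so the 5′ end of a gene could not be told from its 3′ end. The region planned was the 5′ end; in its place, the end with the higher CpG density was taken for each gene, from 1000 bp outside the gene to 500 bp inside it, and is called the CpG-rich gene end. Of all autosomal and X-linked genes, 3307 shared windows with another gene. Counts at a gene end or window are given as CPM, the count relative to the scaled library size. They measure captured DNA and not a percent of methylated cytosines, so a sequence that is missing from a genome, or that maps poorly to the B6 reference, also lowers them.

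Counts were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Features passed filterByExpr with a minimum count of 10, libraries were scaled by TMM, and 1 quasi-likelihood model with 15 groups of strain and tissue was fitted to all 46 libraries. Adjusted p-values are Benjamini-Hochberg values over the 14171 gene ends or 1172069 windows that passed the filter, with a threshold of 0.05. Chromosomes X and Y were left out because the labels give no sex. Averages over strains weight the strains equally. The standard error of a log2 difference is its size divided by the square root of the F statistic. These p-values measure the spread between samples, since each library is labelled as its own sample. The labels give no animal, so samples of the same mouse, if there are any, were treated as independent.

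Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The 15 lists covered genes methylated in colorectal cancer, Wnt pathway genes, homeobox, germline and imprinted genes, DNA methylation enzymes, housekeeping genes, and markers of epithelial, immune, stromal and endothelial cells. Lists, contrasts, tests and the rule for named genes were fixed before the data were examined.

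The rule named up to 10 gene ends per direction for the adenoma comparison, with the same sign in 5 of 5 strains, and at least 2 members of each list. It also named 3 gene ends for Apc Min against wild type, 5 for the difference between strains, 5 windows per direction for adenomas, and 3 windows per direction and chromosome class for strains. Apc was named in every group. Results for some genes that the rule named are not reported here. Other names in the text were chosen after their values were seen and are given as such.

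The tests were checked on simulated counts drawn from the real means and library sizes, with 100 features changed 2-fold and 100 changed 4-fold. At 14171 gene ends, the adenoma comparison over all strains recovered 85% of the 2-fold and 100% of the 4-fold changes, with 10 false calls of 195. In B6 alone these shares were 37% and 81%, with 5 false calls of 123. In C5 alone they were 32% and 90%, with 16 false calls of 138. For Apc Min against wild type the shares recovered were 83% and 100%, with 5 false calls of 188. The simulated libraries varied independently, with no structure by label number. Among unchanged gene ends of that simulation 5.32% had an unadjusted edgeR p under 0.05. In the real comparison 386 of 14171 did, a smaller share, so recovery there may be lower than simulated. Among 20000 drawn windows, C5 against B6 recovered 14% and 63%, with 7 false calls of 84. The adenoma comparison recovered 79% and 98% there, with 6 false calls of 183.

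As a check for duplicated libraries, the 51 pairs of libraries within groups were compared at gene ends. The squared difference over its counting variance ran from 0.992 to 2.93 with a median of 1.30, where counting error alone gives 1. No pair lay far below counting error, as a library entered 2 times would.

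Alternatives were planned for scaling, test, filter, region, samples in the model, the first number of the sample label, chromosome X and left-out libraries. Those chosen after seeing the data were the share of counts in CpG-dense windows as a covariate, leaving out 6 libraries low in that share, the other gene end, an older form of the quasi-likelihood test, and Apc Min tissue in place of wild type mucosa for strains. The first label number is 1 of 9 values, and the labels do not say whether it marks a batch. Among C5 and C5F1 libraries it was 12 or 16, and among B6 libraries 16 occurred once. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.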

Results

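Methylated DNA was captured and counted for 46 libraries of mouse intestine in 15 groups of strain and tissue. B6 had 5 adenomas, 3 samples of normal mucosa from mice with the Min allele of Apc (Apc Min), and 4 samples of wild type mucosa. B6xPWD, C5 and C5F1 each had 3 libraries of each of these tissues, C1_5F1 had 2 adenomas and 2 samples of normal mucosa, and PWD had 3 samples of wild type mucosa. Total counts per library were 15023537 to 27842607 in B6, 16246061 to 22712896 in B6xPWD, 18046653 to 24158323 in C5, 15114668 to 23495837 in C5F1, 8358806 to 15653236 in C1_5F1 and 22831334 to 25730798 in PWD. CPM values are means with the SD between libraries, log2 differences are given with their standard error, and adjusted p-values are from edgeR. Positions are in mm10.

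Adenomas and normal mucosa of Apc Min mice were compared to find methylation that differs with tumour formation. At CpG-rich gene ends, Itpka, which encodes an inositol trisphosphate kinase, rose by 1.48 ± 0.28 (log2) over the 5 strains, with an adjusted p of 0.0121. In B6 its level was 0.677 ± 0.170 CPM in adenomas (n = 5) and 0.185 ± 0.0564 CPM in normal mucosa (n = 3). The difference was above 0 in 5 of 5 strains, as the rule for named genes required. Creb3l1, which encodes a transcription factor held in the endoplasmic reticulum, fell by 0.77 ± 0.14 (adjusted p 0.00630), Plek2 fell by 0.74 ± 0.15 (0.0137), and the secreted phospholipase gene Pla2g10 fell by 0.58 ± 0.12 (0.0137). The regions were 2:119741337 to 119742836 for Itpka, 2:92023671 to 92025170 for Creb3l1, 12:78906673 to 78908172 for Plek2 and 16:13730595 to 13732094 for Pla2g10. Of the 14171 gene ends tested, 1 rose, 3 fell, and 678 had an unadjusted p under 0.05. Here and below, a share of about 0.05 of the features tested would be expected with no differences, and 678 lies under it. The difference at Plek2 was -1.06 ± 0.27 in B6 and -0.014 ± 0.27 in C5, and at Pla2g10 it was -0.90 ± 0.24 in B6 and -0.049 ± 0.34 in C1_5F1. With 2000 bp either side of the gene end Itpka was at 0.52 and missed the threshold, and at the other ends of the genes, which are other regions, Itpka was at -0.065, Plek2 at 0.042 and Creb3l1 at -0.056. All 4 missed the threshold when C1_5F1 adenoma 5_4 or normal mucosa 5_1 was left out, and with the first number of the sample label as a factor 12 gene ends passed, these 4 among them.

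**Figure D1:**
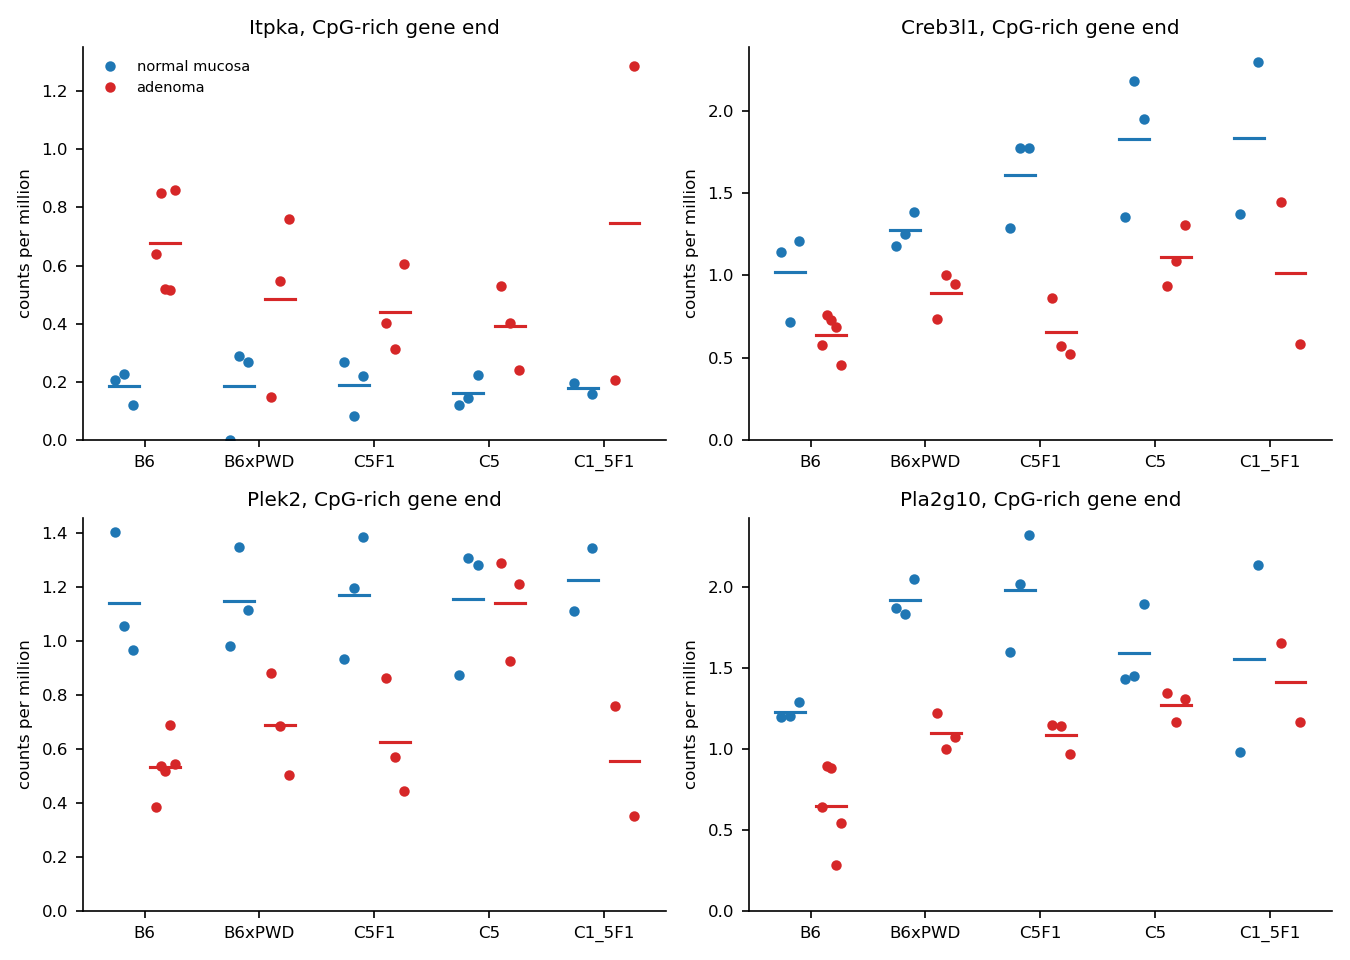
CPM at the CpG-rich gene ends of Itpka, Creb3l1, Plek2 and Pla2g10 by strain, in normal mucosa (blue) and adenomas (red) of Apc Min mice; points are libraries and lines are group means. In B6 the mean at Itpka was 0.185 in normal mucosa and 0.677 in adenomas.

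At single windows of 250 bp, 11 of 1172069 passed in adenomas over the 5 strains, of which 6 rose and 5 fell. A pair of neighbouring windows shared by Otop2 and Ush1g rose by 1.83 ± 0.25 (11:115318751 to 115319000, adjusted p 0.000190) and 1.82 ± 0.28 (11:115318501 to 115318750, 0.00431). In B6 the first of these had 1.55 ± 0.210 CPM in adenomas (n = 5) and 0.294 ± 0.0956 CPM in normal mucosa (n = 3). A window in Mettl16 rose by 1.61 ± 0.26 (11:74823251 to 74823500), a window 587 bp from Itpka rose by 2.01 ± 0.36 (2:119741501 to 119741750), and a window in Onecut3 was at 0.318 ± 0.262 CPM in 16 adenomas of all strains and 0.0320 ± 0.0376 CPM in 14 samples of normal mucosa (10:80503001 to 80503250). A window in Dusp6, which encodes a phosphatase of ERK kinases, fell by 0.98 ± 0.17 (10:99266001 to 99266250). Windows in Ablim1 (19:57092501 to 57092750) and 7275 bp from Foxq1 (13:31568251 to 31568500) fell by 0.73 ± 0.13 and 0.84 ± 0.15. The other windows that passed lay in Zfp503, where 1 rose, and near Auh and Pth, where 2 fell. At an unadjusted p under 0.05 there were 49564 windows, and with the first label number as a factor 139 passed.

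None of the members of the 15 gene lists passed over all gene ends with edgeR. Among 62 genes methylated in colorectal cancer, 40 had a difference above 0, with Hic1 at 0.46 ± 0.18 and Cdo1 at -0.73 ± 0.30. Of 127 homeobox genes 80 were above 0, among them Zic4 at 0.46 ± 0.15 and Hoxa2 at 0.37 ± 0.13. Of 39 imprinted genes 28 were above 0, and Ndn, which encodes necdin, was at 0.47 ± 0.12, the 1 imprinted gene that passed when adjusted over the list alone. Of 50 germline genes 39 were above 0, with Tdrd6 at 0.37 ± 0.16 and Fkbp6 at 0.26 ± 0.13. Both the imprinted (adjusted p 0.0165) and the germline list (0.0124) were higher than other gene ends by limma's camera at the preset correlation, while adjusted p = 0.810 with an estimated correlation for both. The other 13 lists did not pass by either form, and no list passed by fry.

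Wnt pathway genes did not pass as lists or singly. Of 20 Wnt antagonists 8 were above 0, with Notum at -0.45 ± 0.16 and Sfrp2 at 0.22 ± 0.15, and the list's median was -0.038. Of 15 Wnt targets and stem cell markers 8 were above 0, with Olfm4 at 0.47 ± 0.26 and Prom1 at -0.25 ± 0.14. Of 13 genes for DNA methylation enzymes and cofactors 6 were above 0, with Dnmt3l at 0.25 ± 0.12 and Cxxc1 at -0.37 ± 0.19. Of 22 enterocyte genes 13 were above 0, with Slc5a1 at 0.35 ± 0.12. Of 18 secretory cell genes 9 were above 0, with Muc2 at 0.29 ± 0.24 and Chga at -0.15 ± 0.13. Of 25 stromal and muscle genes 14 were above 0, with Pdgfrb at -0.41 ± 0.15 and Postn at -0.41 ± 0.22. Of 17 endothelial genes 11 were above 0, with Tek at 0.27 ± 0.17 and Esam at 0.19 ± 0.12. Immune lists had 8 of 17 B cell genes above 0 (Blnk -0.50 ± 0.22, Bank1 0.24 ± 0.19), 15 of 23 T cell genes (Cd69 -0.30 ± 0.14, Cd4 -0.42 ± 0.20) and 9 of 21 myeloid genes (Cd68 -0.18 ± 0.083, Coro1a -0.34 ± 0.20). Of 5 housekeeping genes 1 was above 0, with Gusb at -0.26 ± 0.19 and Ywhaz at -0.17 ± 0.17. Adjusted over the list alone, 0 members of these 11 lists passed with edgeR. Their members at an unadjusted p under 0.05 were 3 T cell and 2 enterocyte genes, 1 each among Wnt antagonists, DNA methylation, B cell, myeloid and stromal genes, and 0 in the other 4 lists.

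The adenoma comparison was also made within each strain. In B6xPWD the gene end of Nradd rose by 2.25 ± 0.41 (9:110623894 to 110625393, adjusted p 0.0141), from 0.684 ± 0.304 CPM in normal mucosa (n = 3) to 3.20 ± 2.65 CPM in adenomas (n = 3), with 6.26 CPM in adenoma 11_5, 1.64 in 16_6 and 1.71 in 18_2. The labels of 11_6 conflict, naming its MeDIP library normal mucosa of Apc Min mice and its input library wild type; 1 gene end passed in B6xPWD without it, 20 without 16_6, 3 without 18_2, and 0 with edgeR without 11_5 (545 at an unadjusted p under 0.05), 16_5 (626) or 18_1 (586). Nradd was the 1 gene end that passed there, with 623 at an unadjusted p under 0.05 and 0 by DESeq2. With edgeR, 0 gene ends passed in B6 (803 at an unadjusted p under 0.05), in C5F1 (516), in C5 (410) and in C1_5F1 (473), and DESeq2 called 0 in B6, C5F1 and C5. Differences between strains in the adenoma effect had the lowest p at Gm38457, Nradd, Ccdc194, Hoxa6 and a region shared by Gbx2 and the neighbouring LOC102637806, of which 0 passed by edgeR (469 gene ends at an unadjusted p under 0.05) or DESeq2. With the first label number as a factor 10 gene ends passed in B6, 10 in B6xPWD and 6 for the difference between strains. Hoxa6 was at 8.76 CPM in adenoma 11_5 and at 0.801 ± 0.184 CPM in the other 8 B6xPWD libraries. Over all 14171 gene ends, adenoma differences of B6 and C5F1 had a Pearson's r of 0.124, and the other 5 pairs of the 4 strains lay between -0.015 and 0.025; these r are across gene ends, which are not independent replicates. At Apc, adenomas of B6 had 1.78 ± 0.571 CPM and normal mucosa 1.82 ± 0.0890 CPM (18:34219297 to 34220796). On chromosome X, 0 of 379 gene ends passed with edgeR, and 19 had an unadjusted p under 0.05.

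Normal mucosa of Apc Min mice was compared with wild type mucosa to ask whether the Min allele goes with methylation changes outside tumours. With edgeR, 0 gene ends passed over the 4 strains with both tissues, 386 had an unadjusted p under 0.05, and DESeq2 called 0. The 3 gene ends with the lowest p were Irx1 at 1.45 ± 0.41 (13:71963224 to 71964723), Prh1 at 0.89 ± 0.25 (6:132571902 to 132573401) and Ppp6r2 at 0.62 ± 0.19 (15:89210451 to 89211950), each with an adjusted p of 0.999. Irx1 had 0.273 ± 0.253 CPM in normal mucosa of B6 Apc Min mice (n = 3) and 0.192 ± 0.129 CPM in B6 wild type mucosa (n = 4). At Apc the B6 wild type level was 1.92 ± 0.450 CPM. Within strains edgeR called 0 gene ends in B6 (439 at an unadjusted p under 0.05), B6xPWD (481), C5F1 (387) and C5 (462), as did DESeq2. Of 1172069 windows 0 passed with edgeR and 33715 had an unadjusted p under 0.05; the lowest p were at windows in Fbn2 (-1.38 ± 0.31), Vav3 (-1.47 ± 0.33) and Myo10 (-1.83 ± 0.40), which were chosen after their values were seen.

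The share of counts in CpG-dense windows differed between libraries with different first numbers of the sample label. It averaged 4.84% in the 11 libraries with number 16, and group means for the other numbers were 5.79% to 7.19%. Of the 11, the 6 lowest, from B6, C5 and C5F1, were at 4.03% to 4.51% and C5F1 16_7 was at 5.21%, while those of B6xPWD (5.53%, 5.54% and 5.94%) and PWD (5.30%) lay within the 5.11% to 6.29% of number 11. Adenomas exceeded normal mucosa by 0.291 percentage points over the 5 strains, with an exact permutation p of 0.356 (two-sided). In B6 the difference was 0.610 points, from 6.27 ± 0.586% (n = 3) to 6.88 ± 0.218% (n = 5), with an exact permutation p of 0.0536. Compared within strain and label number, adenomas were higher in 7 of 10 pairs, by 0.188 points on average.

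**Figure D2:**
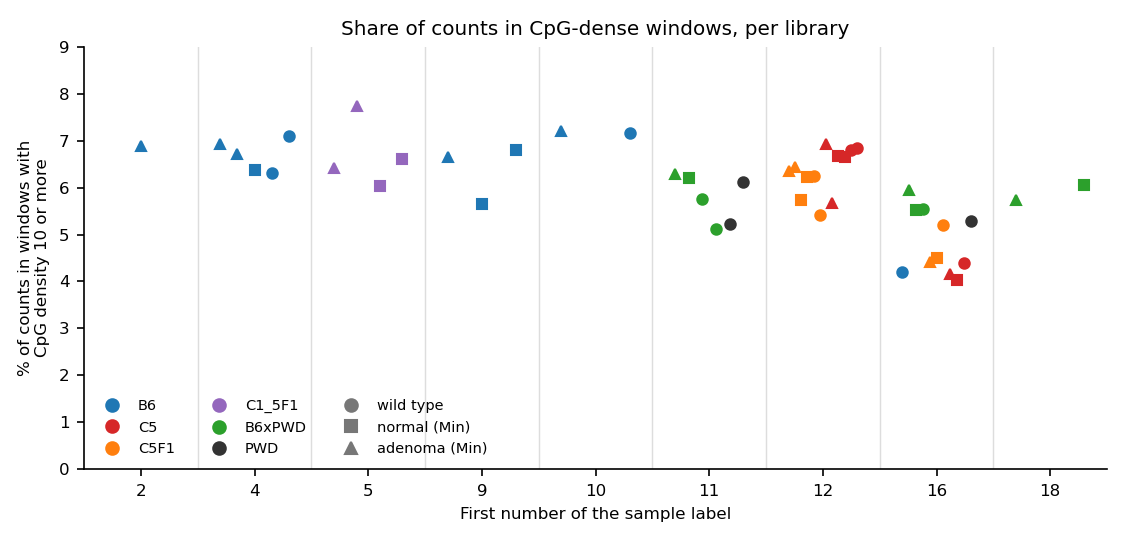
Percent of counts in windows with a CpG density of 10 or more, by the first number of the sample label; each point is a library, coloured by strain, with its shape giving the tissue. Libraries with number 16 averaged 4.84% and those with number 12 averaged 6.34%.

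Wild type mucosa of PWD and B6 mice was compared to map differences between the parent strains. PWD carried 3.63 ± 0.443 CPM (n = 3) at a window 33876 bp from Ccr1 where B6 had 0.0713 ± 0.0314 CPM (n = 4), and B6xPWD 2.43 ± 0.297 CPM (n = 3, 9:123928001 to 123928250). A window in Oip5 had 3.30 ± 0.171 CPM in PWD and 0.0121 ± 0.0241 CPM in B6 (2:119618001 to 119618250). In the other direction, a window in Qtrt2 had 2.31 ± 0.184 CPM in B6 and 0 in PWD (16:43875001 to 43875250), and windows near Tcte2 (17:13591001 to 13591250) and Tmem125 (4:118548001 to 118548250) fell in PWD by 5.03 ± 0.32 and 5.06 ± 0.37. In all, 243570 of 1172069 windows passed, of which 93587 rose in PWD and 149983 fell. In windows with a CpG density of 10 or more, 20.5% fell and 5.25% rose, and in windows with a density under 2, 7.14% fell and 9.63% rose. On chromosome 5, 59.8% of the 13736 windows that passed rose, against 37.1% of those on other autosomes. Chromosome 5 as a whole held 5.57% to 5.64% of the counts in PWD and 4.965% to 5.36% in B6 wild type mucosa. In C5 wild type mucosa it held 4.90% to 5.16%. Such a shift of the whole chromosome in PWD adds to the rises there, and how far was not tested. With the first label number as a factor 127192 windows passed; a comparison within a number holds too few samples, since 16_8 is the 1 B6 wild type library with a number found in PWD, B6xPWD, C5 or C5F1.

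In the F1 cross of B6 and PWD, 21012 windows passed against B6 wild type, of which 15247 rose and 5765 fell. With the first label number as a factor 2472 passed, of which 1245 rose and 1227 fell. A window near Pdia4 had 3.31 ± 0.268 CPM in B6xPWD (n = 3), 4.59 ± 0.149 CPM in PWD (n = 3) and 0.197 ± 0.0512 CPM in B6 (n = 4, 6:47776501 to 47776750). A window in Prdm1, which encodes a transcription factor of intestinal maturation, had 2.84 ± 0.270, 2.99 ± 0.113 and 0.125 ± 0.0950 CPM (10:44498251 to 44498500). A window near Sncg fell by 2.69 ± 0.38 (14:34367751 to 34368000), a window in Lpar1 fell by 2.92 ± 0.45 (4:58538751 to 58539000) and a window in Prom1 fell by 4.02 ± 0.64 (5:43997751 to 43998000). Scaled so that B6 wild type is at 0% and PWD at 100%, the 6 Apc Min libraries of B6xPWD lay at 47.5 ± 2.25% over 82393 windows at least 2-fold higher in PWD and at 47.5 ± 1.31% over 142350 windows at least 2-fold lower. The 8 B6 Apc Min libraries, which did not enter the choice of windows, lay at 5.50 ± 1.31% and 4.41 ± 2.13%.

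**Figure D3:**
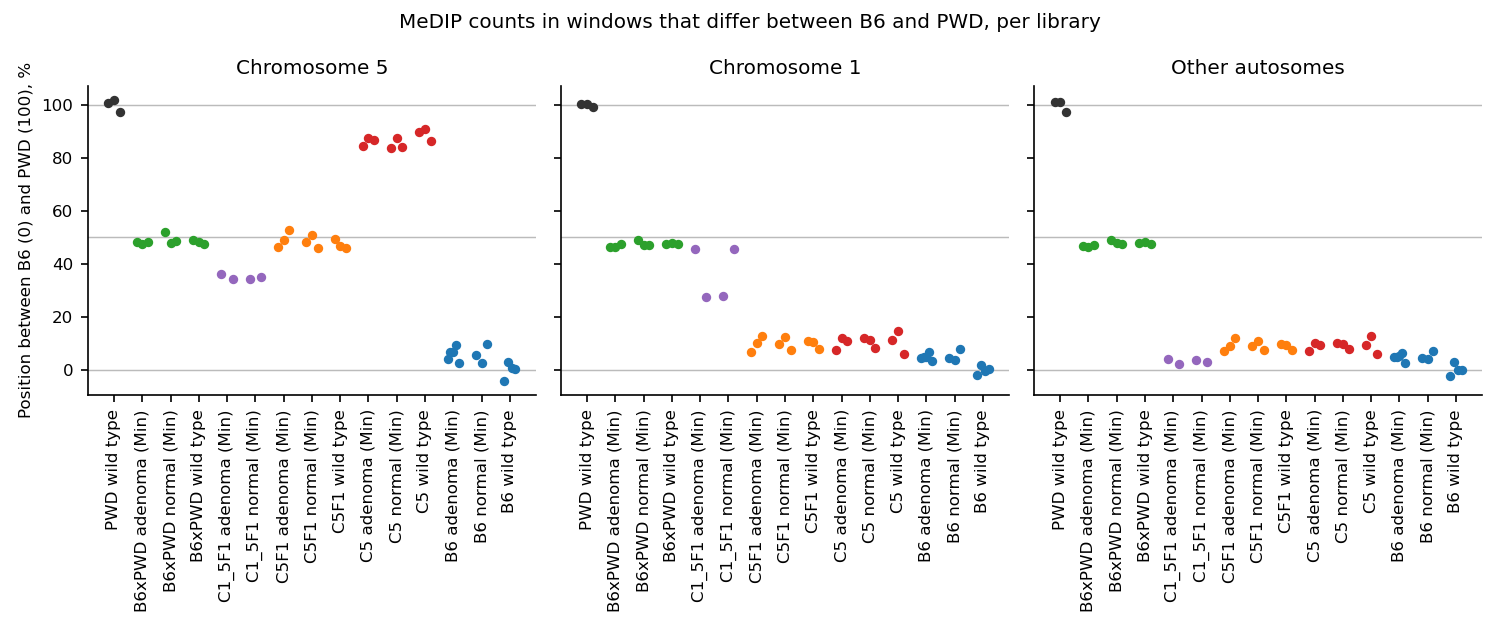
Position of each library between B6 wild type (0%) and PWD (100%) over windows that passed between PWD and B6 with at least a 2-fold difference, for chromosome 5, chromosome 1 and the other autosomes. On chromosome 5 the wild type mean was 89.0% in C5 and 47.3% in C5F1, and on chromosome 1 the C1_5F1 adenomas averaged 36.6%.

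C5 mice carry PWD chromosome 5, so C5 and B6 were compared to separate windows on that chromosome from the rest of the genome. A window in Mmab, next to Mvk, had 3.05 ± 0.827 CPM in C5 wild type mucosa (n = 3), 5.99 ± 0.542 CPM in PWD (n = 3), 1.43 ± 0.407 CPM in C5F1 (n = 3) and 0 in B6 (n = 4, 5:114443751 to 114444000). Both genes encode enzymes, Mvk of the mevalonate pathway and Mmab of cobalamin metabolism. A window whose nearest coding gene was Stim2 had 0.0700 ± 0.0402 CPM in C5, 0.0873 ± 0.0452 CPM in PWD, 0.773 ± 0.227 CPM in C5F1 and 1.49 ± 0.138 CPM in B6 (5:54264501 to 54264750). On chromosome 5, 6621 of 62272 windows (10.6%) passed in C5, of which 3137 rose and 3484 fell, and elsewhere 3704 of 1109797 (0.334%) passed, of which 2871 rose and 833 fell. With the first label number as a factor 1073 and 127 passed. On the scale from B6 to PWD, C5 wild type libraries lay at 89.0 ± 2.28% on chromosome 5, with 77.1 ± 4.00% over windows higher in PWD and 101 ± 0.692% over windows lower in PWD. C5F1 lay at 47.3 ± 1.71%, with 41.5 ± 1.62% and 53.2 ± 1.86%. The larger share of counts on chromosome 5 in PWD, given above, enters these values. On autosomes other than 1 and 5 the values were 9.28 ± 3.38% and 8.93 ± 1.23%, and B6 Apc Min normal mucosa lay at 5.32 ± 1.65%.

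C5 also differed from B6 outside chromosome 5. A window shared by Rfxank and Nr2c2ap had 0 CPM in B6 wild type mucosa, 1.4998 ± 0.647 in C5, 0.673 ± 0.329 in C5F1 and 1.30 ± 0.241 in PWD (8:70131251 to 70131500). A window 50484 bp from Cldn18 had 1.06 ± 0.119 CPM in B6, 0 in C5, 0.395 ± 0.195 in C5F1 and 0.937 ± 0.110 in PWD (9:99767751 to 99768000). In C5F1, 354 windows passed, of which 277 lay on chromosome 5, with 270 that rose, and 77 elsewhere, with 76 that rose; with the first label number as a factor 3 passed. Among them, a window in Tbc1d1 had 0.692 ± 0.141 CPM in C5F1 and 0 in B6 (5:64290751 to 64291000), a window in Stk32b fell by 1.92 ± 0.37 (5:37548501 to 37548750), and a window in Cfap54 fell by 2.73 ± 0.56 (10:92817001 to 92817250).

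The same strains were compared in Apc Min tissue, a comparison chosen after seeing the data. C5 tissue had 18818 windows that passed against B6, 12400 of them on chromosome 5, and C5F1 tissue had 6828, with 2760 on chromosome 5. B6xPWD tissue had 81834 windows. C1_5F1 tissue had 1427, with 492 on chromosome 5 and 443 on chromosome 1. Between C5 and C5F1 tissue, 754 windows on chromosome 5 and 9 on other autosomes passed. At the window in Mmab, C1_5F1 had 2.54 ± 0.560 CPM in adenomas (n = 2) and 1.67 ± 0.0557 in normal mucosa (n = 2), and at the window named for Stim2 it had 0.911 ± 0.0949 and 0.818 ± 0.00368 CPM.

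**Figure D4:**
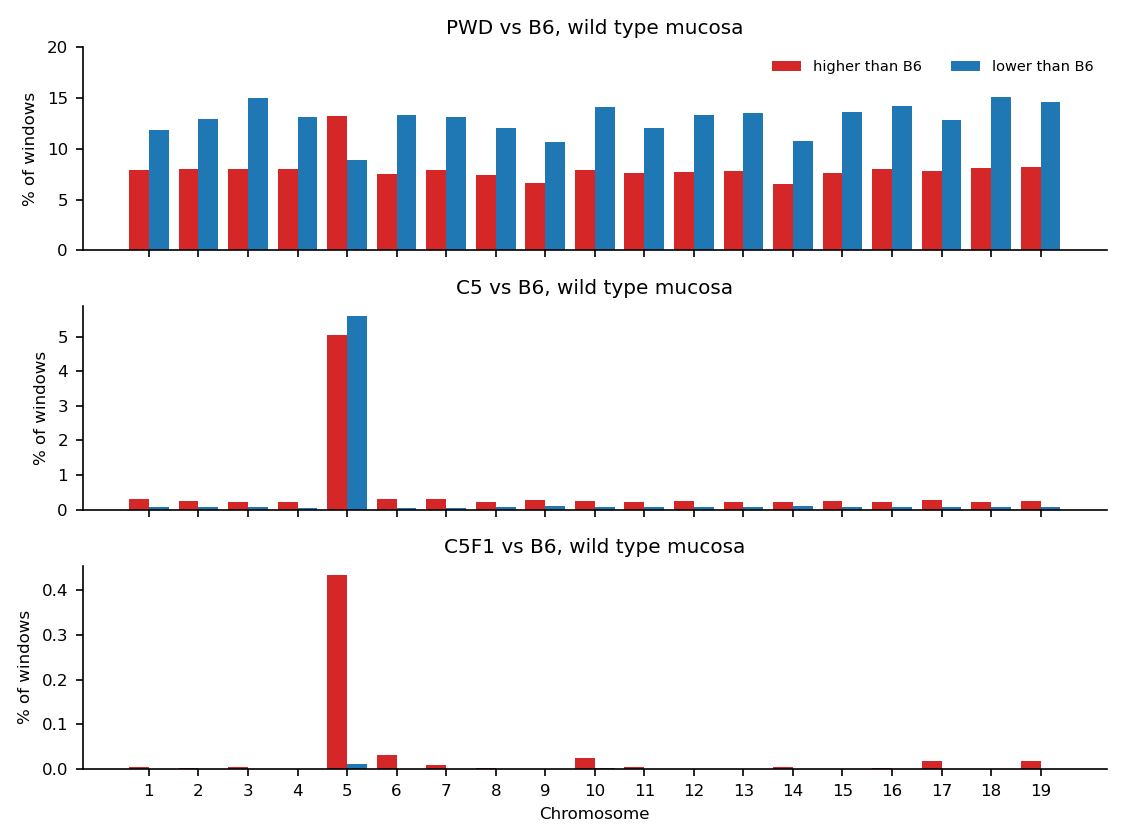
Percent of tested windows on each autosome that passed as higher (red) or lower (blue) than B6, in wild type mucosa of PWD, C5 and C5F1; the panels have different vertical scales. On chromosome 5, 10.6% of windows passed in C5 and 0.445% in C5F1.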

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

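Tests chosen only after the result was seen were those of windows lower in PWD by size of the fold, of positions along chromosomes 1 and 5, and of splits within label number.

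Among 92 tests for a library far from the others of its group, 1 library stood out, where chance gives about 1 in 20. At the gene end of Cd69, an activation marker of T cells, the B6 adenoma 4_1 had 0.940 CPM and the other 4 B6 adenomas 1.13 to 1.21 CPM. On chromosome 1, the C1_5F1 libraries, which entered no strain comparison planned before the data were examined, lay at 36.6% (adenomas, n = 2) and 36.8% (normal mucosa, n = 2) of the way from B6 to PWD. B6 libraries lay between -1.94% and 7.87% there.

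Outside chromosome 5, 3704 windows passed between C5 and B6 wild type mucosa, among them the runs at Glis3 and Anks1b, against 77 in C5F1; the 3704 became 470 without C5 12_11 and 14017 without C5 16_1, and in Apc Min tissue C5 had 6418 and C5F1 4068. An effect of PWD chromosome 5 on other chromosomes that grows with its copies would need C5 to exceed C5F1 in Apc Min tissue, which shares no library with that comparison. There the median log2 difference between C5 and C5F1, signed by the call, was 0.0020 at windows outside chromosome 5 and 0.756 at those on it, a ratio of 0.00266, which argues against an effect of that kind at most of these windows, but not against an effect that 1 copy gives in full. With the share of counts in CpG-dense windows as a covariate 21705 windows passed there, which argues against that share as the cause. The same ratio could also come from a batch marked by the first label number, which C5 and C5F1 share and most B6 libraries do not. With that number as a factor the median difference from B6 in C5 Apc Min tissue went from 0.374 to 0.088 at these windows. On chromosome 5 it went from 1.84 to 1.76, while calls fell both outside it (to 127) and on it (to 1073). That fit links C5 to B6 only through B6 wild type 16_8. Since 16_8 also took part in choosing these windows, the change cannot decide for a batch. A batch, an effect of 1 copy, and differences between the B6 mice of the crosses and the other B6 mice, as at Glis3, stay open.

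More windows were lower than higher in PWD, as at Qtrt2 and near Tcte2. Reads of PWD sequence that map poorly to the B6 reference, or sequence absent from PWD, would lower the input library of the B6xPWD adenoma 11_5 at these windows too. Input reads there were 0.834 times those of windows that did not differ, matched on CpG density. Had lost PWD reads made up the whole difference at each window, the ratio would be 0.627. Loss may thus explain part of the windows, and methylation cannot be told apart from it at the rest. By size of the difference the ratio was 0.916 under 4-fold, where loss as the whole difference would give 0.688. It was 0.817 from 4-fold to 16-fold, against 0.580, and 0.534 over 16-fold, against 0.515. At windows over 16-fold lower in PWD the input is thus consistent with lost or absent sequence, under a limit written after these values had been seen.

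In B6xPWD more windows were higher than lower than in B6, as at Pdia4 and Prdm1. The lowest share of calls that were higher in B6xPWD, with library sizes alone or factors from 10 kb bins, was 67.9%, which argues against the scaling as the cause. With the first label number as a factor 1245 windows were higher and 1227 lower, so a batch marked by that number stays open as a cause of the excess. If 1 PWD allele adds 0.5 of the difference between the parents, Apc Min libraries of B6xPWD, which took no part in the calls, should lie between 35% and 65% of the way from B6 to PWD. They lay at 47.5% over windows lower in PWD and at 47.5% over windows higher in PWD, within that range. On chromosome 18 alone, B6xPWD adenomas averaged 41.1%, and normal and wild type mucosa 48.0% each. Whether a position midway between the parents accounts for the excess of higher windows was not tested.

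Splits of the samples, with the real one counted among them, were made for each comparison. Their number was at most 40, fewer than first intended, to save run time. It was lowered further for a time after the first result had been seen and then put back to 40. For adenomas at gene ends, 2 of 40 splits, the real one included, gave as many calls as the real 4, so chance is not excluded among all splits, and the highest other split gave 427. That split exchanged C5 adenoma 12_3 with C5 normal mucosa 16_2 among others, which points to a structure of the samples. Among splits that exchange libraries only within strain and label number, 1 of 40, the real one, reached 4 calls (highest other 0). With that number as a factor 1 of 40, the real one, reached 12 (highest other 5). These splits were chosen after the result was seen, and 1 of 40 is the smallest share they can give. They argue against chance there without excluding it. Where the real count was 0 every split gives as many, so the splits say nothing of chance: 40 of 40 for the difference between strains (highest other 625, which points to a structure of the samples too), 40 of 40 for Apc Min against wild type (highest 13), 40 of 40 for adenomas in B6 (highest 1), 35 of 35 for Apc Min against wild type in B6 (highest 0), and 40 of 40 for Apc Min against wild type among 20000 drawn windows (highest 1). With 3 against 3 libraries the 10 splits are too few: the real and the highest other counts for adenomas were 1 and 27 in B6xPWD (3 splits as large), 0 and 2 in C5F1 (10 splits) and 0 and 336 in C5 (10 splits), a split that put both libraries numbered 16 in the same group. For Apc Min against wild type they were 0 and 3 in B6xPWD, 0 and 0 in C5F1, and 0 and 2 in C5, each with 10 splits as large. Among 20000 drawn windows, adenomas had 1 call, with 3 of 40 splits as large (highest 2), so chance is not excluded. Against B6, the real split alone reached its count for PWD (4247 calls, 1 of 35 splits, highest other 2566). The same held for B6xPWD (431, 1 of 35, highest 201) and C5 (187, 1 of 35, highest 97). As 1 of 35 is the smallest share possible, these splits argue against chance without excluding it. For C5F1 (3, 2 of 35, highest 3) another split did as well. It set the C5F1 libraries and B6 16_8 against the other B6 libraries, so it is close to the real split and says little of chance. In C5F1 Apc Min tissue, 94.9% of the 13736 chromosome 5 windows that passed between PWD and B6 had the same sign against B6. This argues against chance for a C5F1 difference on chromosome 5, while elsewhere chance stays open. In these 4 the highest other split grouped B6 library 16_8 with the other strain.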

How the results depend on the processing

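The p-values rest on few libraries, 2 to 5 per group, and on depth: at windows of 250 bp, C5 against B6 recovered 14% of simulated 2-fold changes, so most differences of that size are missed. In fits that leave out a library the spread is pooled over all groups, and a group left with 1 sample is assumed to vary like the others. Alternatives chosen after seeing the data were the share of counts in CpG-dense windows as a covariate, the fit without the 6 libraries low in that share, the other gene end, the older quasi-likelihood method, Apc Min tissue in place of wild type mucosa, and list tests with the label number or that share. Not run were a minimum count of 5 for windows, 12_10 and 12_10A as 2 libraries, since the table has no column for 12_10, and the Y share as a covariate, since no windows of chromosome Y were tested. No paired analysis by animal was possible because the labels give no animal. The first label number pairs 1 adenoma with 1 normal mucosa in B6xPWD at 11, 16 and 18; as a factor in the model, it gave 10 calls in B6xPWD and 12 over all strains. Deviations of these libraries from their group means had an r of 0.139, 0.0825 and 0.0528 within the pairs, and each correlated best with its own number, a hint from the data and not from the design. Where a value moved, the cause was not tested, except that the other gene end is another region and the label number leaves few libraries to compare within a number.

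Adenoma and Apc Min comparisons within C5 and C5F1, and Apc Min against wild type in every strain and over strains, stayed at 0 calls under each alternative. The median r of adenoma differences between strains, 0.00519, ranged from 0.000618 to 0.0226. Of 577 values of named gene ends under alternatives, 544 kept their direction and their side of the threshold, 5 missed it, 11 newly passed and 17 changed sign. Of 331 values of named windows 308 kept both and 23 missed the threshold.

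At gene ends, adenomas against normal mucosa over all strains had 4 calls. This became 12 with the label number as a factor (7 higher, 5 lower), 11 with the CpG-dense covariate (4 higher, 7 lower), 10 without the 6 low libraries, 10 without C1_5F1, and 0 at the other gene end (725 at an unadjusted p under 0.05 by edgeR; DESeq2 was not run there). In B6 the 0 calls became 10 with the label number, 41 with the covariate, 29 without the 6 libraries, 1 with 500 bp either side of the gene end, 6 with 2000 bp either side and 35 with only the groups compared. In B6xPWD the 1 call became 10 with the label number, 8 with the covariate, 3 without the 6 libraries, 2 with 500 bp and 2 at the other gene end. It became 0 by edgeR with library size alone (584 at an unadjusted p under 0.05), TMM on 10 kb bins (554), 2000 bp (771) and only the groups compared (401), and 0 by DESeq2 (325). The difference between strains in the adenoma effect, with 0 calls, had 6 with the label number, 16 with the covariate and 4 without the 6 libraries. Gene lists called by camera, 2 in all, became 0 with an estimated correlation, 0 with fry and 0 with the CpG-dense covariate, where the adjusted p of the imprinted and the germline list was 0.767.

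With 2000 bp either side, Cd4 was at 0.0063 and Cxxc1 at 0.067, and Itpka, at 0.52, missed the threshold. At the other gene end, the sign changed at Itpka (-0.065), Plek2 (0.042), Cd4 (0.032), Cdo1 (0.13), Tdrd6 (-0.060), Fkbp6 (-0.75), Hoxa2 (-0.024), Ndn (-0.021), Coro1a (0.098), Muc2 (-0.048), Chga (0.36), Notum (0.088) and Sfrp2 (-0.055) for adenomas, and at Irx1 (-0.098) and Ppp6r2 (-0.030) for Apc Min against wild type.

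At windows, the 11 adenoma calls became 139 with the label number (53 higher, 86 lower), 144 with the covariate (36 higher, 108 lower), 64 without C1_5F1, 45 without the 6 libraries, 24 with windows summed in pairs, and 5 with TMM on 10 kb bins (4 higher, 1 lower, against 6 and 5). With the label number, PWD against B6 wild type had 127192 windows, B6xPWD 2472 (1245 higher, 1227 lower), C5 1200 (1073 on chromosome 5 and 127 on other autosomes) and C5F1 3 (2 and 1). With the CpG-dense covariate, B6xPWD had 42539, C5 32172 (10467 on chromosome 5 and 21705 on other autosomes) and C5F1 899 (593 and 306). Without the 6 libraries, B6xPWD had 35293 (20181 higher, 15112 lower), C5 29883 (21862 on other autosomes) and C5F1 669 (311 on other autosomes). With Apc Min tissue in place of wild type, B6xPWD had 81834, C5 18818 (12400 on chromosome 5 and 6418 on other autosomes) and C5F1 6828 (2760 and 4068). With a minimum count of 20, PWD had 79777, B6xPWD 8004, C5 4965 (3001 on chromosome 5 and 1964 on other autosomes) and C5F1 40 on other autosomes. With TMM on 10 kb bins, C5F1 had 229 (173 on chromosome 5). With a mean of at least 1 count in both groups, C5F1 had 109 (103 on chromosome 5 and 6 on other autosomes). On other autosomes, the split of 2871 higher and 833 lower in C5 was 2024 and 980 with library size alone, and 1672 and 891 with TMM on 10 kb bins.

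Leaving out 1 library at a time, adenoma calls at gene ends over all strains ranged from 0 (without C1_5F1 adenoma 5_4 or normal mucosa 5_1) to 5. Adenoma calls in B6 ranged from 0 to 2 (1 without 4_1 or 9_4, 2 without 10_2), in B6xPWD from 0 (without 11_5, 16_5 or 18_1) to 20 (without 16_6, and 3 without 18_2), and for the difference between strains from 0 to 8 (without 16_6). They stayed at 0 in the other gene end comparisons. PWD windows ranged from 177581 to 228226. B6xPWD windows ranged from 9946 (without 11_3) to 20948, with 10703 without 11_4, 11952 without 16_4, 13042 without B6 4_5, 13098 without B6 4_4 and 13159 without B6 10_1. C5 windows ranged from 3966 (without 12_11) to 21192 (without 16_1), with 5994 without 12_1 and 6461 without B6 10_1. On chromosome 5 they ranged from 3496 (without 12_11) to 7175, with 4164 without 12_1. On other autosomes they ranged from 470 (without 12_11) to 14017 (without 16_1), with 1578, 1819 and 2114 without B6 10_1, 4_4 and 4_5 and 1830 without 12_1. C5F1 windows ranged from 159 (without B6 10_1) to 254 (without B6 16_8), with 165, 187 and 186 without 12_10A, 12_12 and 16_7 and 174 and 181 without B6 4_4 and 4_5. On chromosome 5 they ranged from 125 to 169, all under the 277 of the full comparison, and on other autosomes from 34 to 85. Fewer samples lower the power of these fits, and the rise in C5 without 16_1 was not explained by a test.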

Other observations

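All places named in this part were chosen after their values were seen, and so were the tests. Among the places outside chromosome 5, 8 runs of neighbouring windows differed between C5 and B6 wild type mucosa. At Glis3 (19:28629501 to 28645500) the summed windows had 0 CPM in B6 (n = 4), 8.12 ± 1.69 in C5 (n = 3), 4.32 ± 0.199 in C5F1 (n = 3), 4.50 ± 0.339 in B6xPWD (n = 3) and 8.22 ± 0.380 in PWD (n = 3). At Anks1b (10:89883751 to 89944750) the values were 0 in B6, 12.5 ± 2.52 in C5, 7.34 ± 1.34 in C5F1, 7.68 ± 0.743 in B6xPWD and 15.9 ± 1.59 in PWD. At Dynlt1b (17:6420501 to 6592250) C5 had 17.8 ± 3.25, C5F1 8.52 ± 0.316, PWD 3.35 ± 0.0756 and B6 0.302 ± 0.0733 CPM. On chromosome 9 (99750001 to 99782250) the order was the other way, with 0.0344 ± 0.0305 CPM in C5, 5.36 ± 0.536 in C5F1, 11.4 ± 1.06 in B6 and 10.8 ± 0.429 in PWD. At Glis3, counts per C5 Apc Min library ran from 1 to 187 in adenomas and from 0 to 166 in normal mucosa. They ran from 4 to 397 and 7 to 416 at Dynlt1b, and from 0 to 111 and 1 to 129 on chromosome 9. At Anks1b they ran from 127 to 263 and 167 to 244. C5 libraries thus differed widely among themselves at Glis3, Dynlt1b and on chromosome 9. The 8 runs held 164 of the 3704 windows that passed outside chromosome 5. Both Glis3 and Anks1b are transcribed in many tissues, and no difference in their expression was measured here.

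Adenoma 11_5 of B6xPWD carried far more counts than the other 8 B6xPWD libraries at 43 gene ends, of which 23 were CpG-dense. The next B6xPWD library, adenoma 18_2, had 1 such gene end. Across strains the next was PWD 11_1 with 4, which was compared with only 2 other libraries. Some of the 43 overlap and share counts, such as Kmt2b and Zbtb32, each with a count of 45. Among the 43, the homeobox gene Cdx1 was at 2.89 CPM against 0.472 ± 0.167, the guanylate cyclase gene Gucy2c at 5.73 against 1.10 ± 0.375 and the keratin gene Krt8 at 2.01 against 0.311 ± 0.0789. The receptor gene Mst1r was at 2.01 against 0.163 ± 0.0703 and Krt7 at 5.24 against 0.607 ± 0.192. By the homeobox list, of which 127 genes were tested, 2 of the 43 were counted as members (Fisher's exact p 0.0567). That count misses some homeobox genes, since Cdx1, Gbx2, Hoxa5 and Hoxa6 were all among the 43, so it does not hold for homeobox genes at large. The input library of the same sample had a median of 7 reads at the 43 gene ends and of 7 at all gene ends.

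Positions between B6 and PWD in bins of 10 Mb differed along chromosomes 1 and 5 in C1_5F1. From 0 to 70 Mb of chromosome 1, the adenoma 5_2 and the normal mucosa 5_1 averaged 46.6% and 45.9%, and the adenoma 5_4 and the normal mucosa 5_3 averaged 2.01% and 3.69%. From 80 to 200 Mb the 4 libraries averaged 44.0% to 45.8%. On chromosome 5 they averaged 46.6% to 48.1% from 0 to 120 Mb and 4.62% to 8.61% from 120 to 160 Mb. Thus 5_1 and 5_2 shared their values on chromosome 1, as did 5_3 and 5_4. The labels do not say whether an adenoma and a normal sample came from the same mouse.

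Chromosome 5 held a larger part of the counts in PWD than in the strains that carry PWD chromosome 5. Relative to B6 wild type mucosa, its tested windows had 1.13 ± 0.00711 times the share of counts in PWD (n = 3), 1.05 ± 0.0115 in B6xPWD (n = 9), 0.982 ± 0.0282 in C5 (n = 9) and 0.993 ± 0.0229 in C5F1 (n = 9). In bins of 10 Mb the PWD value ran from 1.06 to 1.19.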
